A study of Homo sapiens with 7 samples.

How the data were processed

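RNA was measured in 7 libraries from Caco2 cells, 4 uninfected and 3 infected with *Encephalitozoon intestinalis*. Per the labels' protocols, cells were grown to confluency in flasks, infected by adding 100 μl of spore suspension and kept for 14 days. RNA was extracted with a column kit, enriched for poly(A) RNA, made into libraries with the NEBNext Ultra II kit and sequenced on a NextSeq instrument as single reads of 75 bases. The labels do not say whether uninfected cells were kept for the same time, or whether replicates were separate flasks.

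The authors deposited 1 table of normalised counts, whose values are CPM, counts scaled to a common total of the reads assigned to genes in each library, with 0.0001 added to every value. This unit was read from the values, since each column sums to between 986520 and 989351 and the lowest value in every column is the added constant. Per the submitters' processing notes the tool was Partek, with no version, and the build hg19. The aligner, the counting rule, the use of strand and the handling of duplicates are not given in the sources used here. The gene coordinates in the table are those of GRCh38: of 27195 genes matched by name and chromosome to GENCODE release 29, 26046 (95.8%) had the same start and end. Coordinates are therefore given as GRCh38.

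The value of 1 read was estimated in each library from the smallest regular step between low values, which gave 13172000 to 15916000 assigned reads per library. Of the low values up to 20 reads, 56.4% to 57.9% lay within 0.1 of a whole read, so the underlying counts are partly fractional and whole reads could not be recovered. A floor of 3 reads came to 0.188 to 0.228 CPM, and such floors cover counting error only, since reads without molecular identifiers are not independent molecules. Estimated reads divided by transcript length gave the reads per base of transcript, for 27614 of 27727 genes. Only 13 of the 18132 tested genes with a length exceeded 1 read per base. The estimated reads in the 13 mitochondrially encoded genes were 10128 to 10275 in every library. A limit near 1 read per base would compress differences of the most abundant transcripts.

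The added constant of 0.0001 was left in the values, and genes with a mean of at least 1 CPM over the 7 libraries were kept (18181 genes, 13908 of them protein coding). Differences between infected and uninfected libraries were tested on log2(CPM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, no covariate and no robust option. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and the threshold was 0.05. A total of 41 gene lists, with 1080 symbols of which 1036 were found in the table, were tested with camera at a preset correlation of 0.01, adjusted over the lists with at least 5 tested members. No list had a call with an estimated correlation. For each list, members past the threshold were also counted with p adjusted over the list alone. Some genes stand in more than a single list. The share of mitochondrially encoded transcripts was compared with an exact two-sided permutation test over the 35 splits of the libraries. Principal components were computed on centred log2 values without scaling.

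The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap and whose mean was at least 5 CPM, and the 3 members of each list with the smallest p, of which the text names some, and results for some of them are not reported here. Genes without an ordinary symbol and genes of the Y chromosome were passed over. The scripts were tested on simulated data with 18181 genes and this comparison. Of 50 genes changed at each size, limma called 25 at 1.5-fold, 40 at 2-fold, 45 at 3-fold and 50 at 4-fold, with 0 in the wrong direction and 12 false calls. Camera called a list of 30 genes raised 1.5-fold and 0 of the other lists. The simulated noise was independent between genes and between libraries. These counts therefore do not show how often correlated lists or paired libraries give false calls.

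The settings varied were pseudocounts of 0.1 and 5, no filter and a minimum mean of 5 CPM, rescaling by trimmed means, by median ratios and by upper quartiles, limma without the trend or with the robust option, the replicate number as a block, leaving out each library in turn, camera on ranks or with an estimated correlation, a test against a 1.5-fold change, and principal components of the 500 most variable genes. Settings chosen after the data were seen were cyclic loess normalisation, estimated reads not scaled to library totals, genes under 0.2 reads per base alone, a correction for 1 read per position, leaving out uninfected libraries 1 and 2 or 3 and 4, and library depth as a covariate. Families of genes sharing the letters before the first digit of their symbol were compared with all other protein-coding genes by a one-sided Fisher's exact test in scipy 1.17.1. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.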

Results

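Polyadenylated RNA was sequenced from Caco2 cells, a human colon cancer line that forms an enterocyte-like epithelial layer once confluent, with and without infection by *Encephalitozoon intestinalis*, a microsporidian parasite that grows inside host cells. The comparison asks which host transcripts differ between infected and uninfected cultures. There were 4 uninfected libraries and 3 infected libraries, the latter kept for 14 days after spores were added. The deposited values are CPM, read counts scaled to a common total per library, for 27727 human genes, and parasite transcripts were not analysed here. The reads assigned to genes, estimated from the smallest step between values, were 15916000, 15663000, 14579000 and 15040000 in uninfected libraries 1 to 4 and 14594000, 13172000 and 13697000 in infected libraries 1 to 3. Infected libraries 2 and 3 were thus the shallowest, and infected library 1 was about as deep as uninfected library 3. A floor of 3 reads corresponded to 0.188 to 0.228 CPM, and it covers counting error only. The labels do not state that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels below are means ± SD over the 4 uninfected and the 3 infected libraries, and log2 fold changes, infected minus uninfected, carry their standard error (SE).

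Among the genes that differed, *CUBN*, *MGAM*, *SLC26A3* and *MAF*, which serve in enterocytes, were lower in infected cells, and *BIRC3*, *CD44*, *PLAU* and 23 of 36 mitotic genes were higher. Lists of digestive enzymes and intestinal transcription factors lay lower at the preset correlation, and the other enterocyte lists did not pass. With an estimated correlation these 2 lists did not pass either (camera adjusted p = 0.732 for each). As many lists were called in 14 of 35 splits of the libraries as in the real split, which is counted among them. The labels give no culture time for the uninfected cells, so a difference in that time cannot be told apart from infection. Of 18181 genes tested with limma, 4472 (24.6%) passed a Benjamini-Hochberg adjusted p of 0.05, with 2103 higher and 2369 lower in infected cells. The test takes the 7 libraries as independent, although some form close pairs, so its p-values may be too small. Within the uninfected group, libraries 1 and 2 against 3 and 4 gave 5797 calls, more than the 4472, with 467 at least 2-fold. Of the 4472 genes, 638 had an estimated change of at least 2-fold, 229 higher and 409 lower. The median absolute log2 fold change of the called genes was 0.54, and 26 genes (6 higher, 20 lower) exceeded a 1.5-fold change in a test against that size. The number of called genes was 1405 without infected library 3, 1430 without infected library 2, 2501 without uninfected library 1, 2903 without uninfected library 2 and 2942 without uninfected library 4. With depth as a covariate it was 555, with the replicate number as a block 2878, and with uninfected libraries 3 and 4 left out 6866. In estimated reads not scaled to library totals, which moved the median of all genes to -0.12, 823 genes were higher and 3140 lower (20.8% higher against 47%). The number changed at least 2-fold was 332 without infected library 2, 382 without infected library 3 and 1260 with uninfected libraries 3 and 4 left out. It was 1059 with a pseudocount of 0.1, 181 with a pseudocount of 5, 417 at a minimum mean of 5 and 185 with depth as a covariate.

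The leading principal component carried 62.7% of the variance and placed every infected library (16.3, 44.4 and 35.1) above every uninfected one (-40.5, -38.1, -3.6 and -13.5). The component after it, with 19.9%, set uninfected libraries 1 and 2 (12.7 and 15.5) apart from uninfected libraries 3 and 4 (-27.8 and -26). On it infected library 1 (15.6) lay beside uninfected libraries 1 and 2. Infected libraries 2 and 3 lay at 5.7 and 4.3, so this component crosses the groups. Between uninfected libraries 1 and 2 on one side and 3 and 4 on the other, limma called 5797 genes, 467 of them at least 2-fold. The labels name no batch, so no value within a batch can be given.

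**Figure D1:**
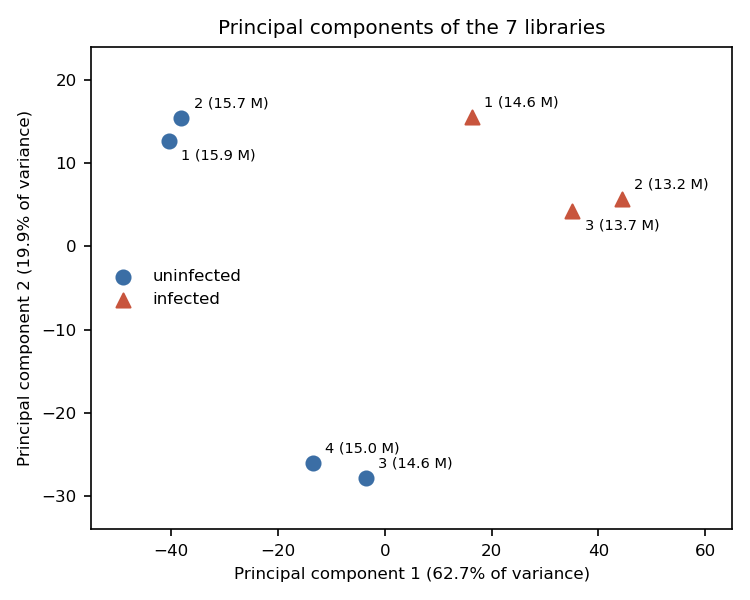
Scores of the 7 libraries on the leading pair of principal components of log2(CPM + 1), each axis labelled with its percent of variance and each point a library coloured by group. The infected libraries lie at 16.3 to 44.4 on the horizontal axis and the uninfected ones at -40.5 to -3.6, with uninfected libraries 1 and 2 apart from 3 and 4 on the vertical axis. Within each group the horizontal score rises as the assigned reads fall.

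The largest rise was that of *MYEOV*, a gene named for its overexpression in myeloma (chromosome 11, 69294138 to 69367726, GRCh38), from 1.38 ± 0.499 to 15.5 ± 4.8 CPM, a log2 fold change of 2.77 ± 0.24 (limma adjusted p = 0.00173). *SEMA6B*, a transmembrane semaphorin (chromosome 19, 4542593 to 4559808), rose from 6.07 ± 3.2 to 39.2 ± 9.37 CPM, by 2.58 ± 0.32 on the log2 scale (limma adjusted p = 0.00327). *AKAP12*, a scaffold for protein kinase A, rose from 6.79 to 32.0 CPM, *NPTX1*, a neuronal pentraxin, from 1.77 to 10.2 CPM, and *GPR3*, a receptor that raises cyclic AMP, from 5.2 to 21.3 CPM. *SPN*, the sialophorin of leukocyte surfaces, rose from 7.82 to 32.6 CPM and *ETV5*, an ETS transcription factor, from 19.5 to 71.6 CPM. Rises were also called for *MICB*, a stress-induced ligand of a natural killer cell receptor, from 11.1 to 51.4 CPM, and for *LYPD3* from 4.01 to 17.6 CPM. The bone morphogenetic protein antagonist *GREM1* rose from 31.5 to 90.9 CPM and hexokinase *HK1* from 13.0 to 44.9 CPM. The *MICB* value is uncertain where reads are shared with its paralog *MICA*. These 11 log2 fold changes ranged from 1.71 to 2.77, with limma adjusted p from 0.00159 to 0.0308. Without infected library 2 or 3 the limma adjusted p was 0.0605 or 0.0534 for *MICB*, 0.0639 or 0.0564 for *LYPD3*, 0.102 or 0.083 for *GREM1* and 0.128 or 0.113 for *HK1*. For *HK1* it was also 0.0693 without uninfected library 1 and 0.0573 without uninfected library 2.

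Among the 12 largest falls was that of *CUBN*, the intestinal receptor for cobalamin bound to intrinsic factor (chromosome 10, 16823964 to 17129831), from 13.4 ± 3.88 to 1.52 ± 0.335 CPM, a log2 fold change of -2.48 ± 0.24 (limma adjusted p = 0.00199). *SLC5A11*, a sodium-coupled inositol transporter (chromosome 16, 24845841 to 24911628), fell from 18.2 ± 4.77 to 2.93 ± 0.544 CPM, a log2 fold change of -2.26 ± 0.21 (limma adjusted p = 0.00191). *BTNL3*, a butyrophilin-like gene of gut epithelium, fell from 12.8 to 2.04 CPM, *BAAT*, which conjugates bile acids, from 14.0 to 2.39 CPM, and *LRRC66* from 14.9 to 1.89 CPM. *HIF3A*, a subunit of hypoxia-inducible factors, fell from 42.0 to 9.13 CPM, the potassium channel gene *KCND3* from 13.5 to 2.59 CPM, *ZFP3* from 16.4 to 3.09 CPM and *TIGD5* from 43.5 to 11.9 CPM. The long noncoding RNAs *LINC00638* and *LINC01133* fell from 15.1 to 1.75 and from 13.6 to 2.12 CPM, and the activin-family gene *INHBE* fell from 17.2 to 3.0 CPM. Log2 fold changes of these 12 genes ranged from -2.65 to -1.94, with limma adjusted p from 0.00191 to 0.0295. The limma adjusted p of *LINC01133* was 0.0618 without infected library 2 and 0.0602 without infected library 3, and that of *INHBE* was 0.112, 0.101 and 0.0678 without infected library 2, infected library 3 or uninfected library 1. Of the 24 genes with the largest rises or falls, 17 kept their call whichever library was left out, and 10 kept it with depth as a covariate.

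**Figure D2:**
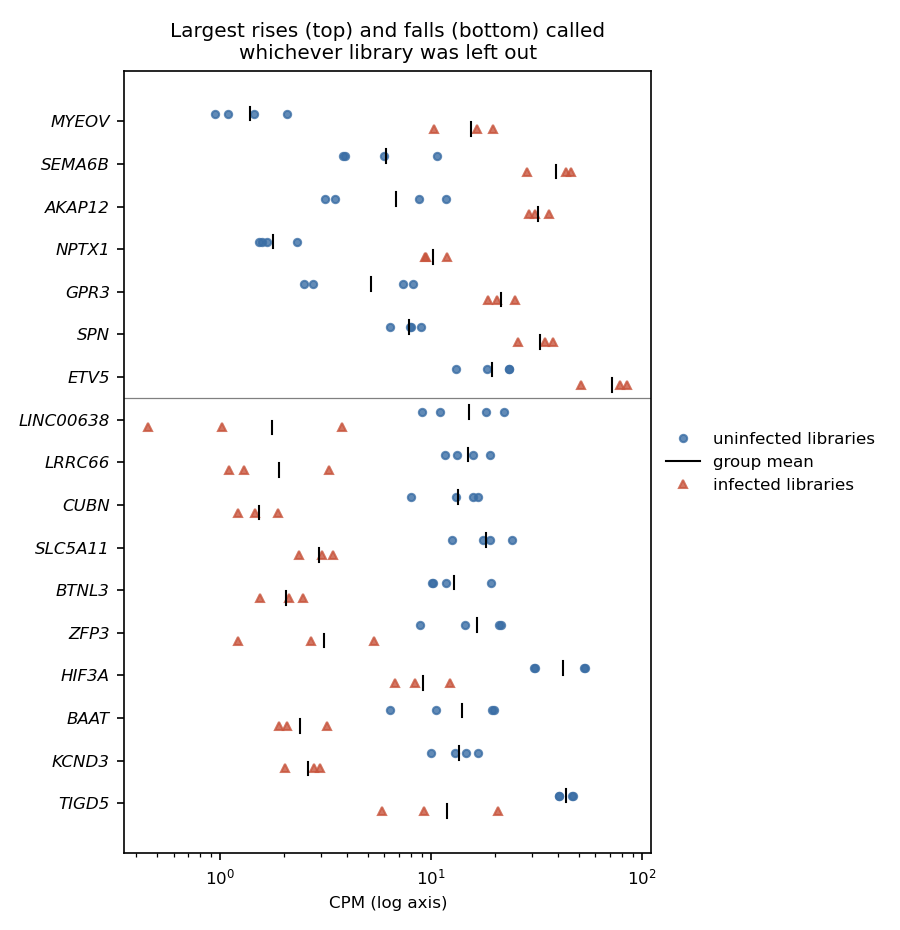
CPM on a log axis of the 17 genes, 7 higher and 10 lower, that kept their call whichever library was left out, among the 24 with the largest rises or falls, each point a library coloured by group and each bar a group mean. These genes were chosen among those whose groups do not overlap, with *MYEOV* at 0.943 to 2.06 CPM in uninfected and 10.3 to 19.7 CPM in infected libraries.

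Of 5 lists of enterocyte genes, those of digestive enzymes and transcription factors lay lower and the other 3 did not pass. Of 14 tested digestive enzymes, 7 fell and 0 rose (7 and 1 adjusted over the list alone), and the list lay lower in infected cells (camera adjusted p = 0.0143, and adjusted p = 0.732 with an estimated correlation). The maltase-glucoamylase gene *MGAM* fell from 10.1 ± 3.24 to 2.26 ± 0.361 CPM, a log2 fold change of -1.72 ± 0.25 (limma adjusted p = 0.00443). The membrane aminopeptidase *XPNPEP2* fell from 39.6 ± 10.8 to 12.5 ± 2.24 CPM (log2 fold change -1.57 ± 0.22). Of 22 intestinal transcription factors, 7 fell and 0 rose (8 and 1 adjusted over the list alone), with a camera adjusted p of 0.0187, and adjusted p = 0.732 with an estimated correlation. *MAF*, a transcription factor of mature enterocytes (chromosome 16, 79585843 to 79600714), fell from 135 ± 25.4 to 40.5 ± 2.18 CPM, a log2 fold change of -1.69 ± 0.14 (limma adjusted p = 0.00173). *PRDM1*, a repressor of adult-type genes in the fetal intestine, fell from 39.5 ± 3.47 to 20.7 ± 2.17 CPM. Without uninfected library 3 the camera adjusted p of the transcription factors was 0.0733. With uninfected libraries 3 and 4 both left out, it was 0.295 for the transcription factors and 0.19 for the enzymes, and among genes under 0.2 reads per base alone it was 0.0673 and 0.2.

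Among 22 nutrient and bile acid transporters, 7 fell and 2 rose (9 and 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0906). The vitamin C transporter *SLC23A1* fell from 74.5 ± 5.25 to 37.6 ± 1.24 CPM, a log2 fold change of -0.96 ± 0.07, and the chloride-bicarbonate exchanger *SLC26A3* from 115 ± 10.6 to 58.9 ± 3.29 CPM, -0.95 ± 0.08. The ileal bile acid transporter *SLC10A2* fell from 2.53 ± 0.545 to 1.01 ± 0.137 CPM. Without uninfected library 2 or infected library 2 this list passed, with camera adjusted p of 0.0272 and 0.0453, and after the correction for 1 read per position (0.0427). In the list for lipoproteins and fat absorption, 5 of 18 genes fell and 0 rose (the same counts adjusted over the list alone), among them *APOB*, the structural protein of chylomicrons, from 613 ± 54.2 to 323 ± 68 CPM (log2 fold change -0.94 ± 0.13). *MOGAT2*, which makes diacylglycerol in enterocytes, fell from 6.43 ± 1.42 to 2.3 ± 0.298 CPM. That list had a median log2 fold change of 0.04, a mean of -0.10 and a test direction of lower (camera adjusted p = 0.711). In the brush border list 3 of 21 genes fell and 1 rose (the same adjusted over the list alone, camera adjusted p = 0.553), with the protocadherin *CDHR5* falling from 181 ± 9.36 to 139 ± 6.21 CPM. Of 28 junction genes, 5 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.0831), and *CLDN12* rose from 90.9 ± 3.83 to 125 ± 9.53 CPM. The junction list passed without uninfected library 3 (camera adjusted p = 0.0194), uninfected library 4 (0.047) or infected library 1 (0.0403). It also passed with no filter (0.0142), with the replicate number as a block (0.0335) and with uninfected libraries 3 and 4 left out (0.00461). With uninfected libraries 1 and 2 left out, the transporters (camera adjusted p = 0.00415) and the brush border list (0.0333) passed as lower. The transporters (2.21e-05), the brush border list (1.54e-05) and the lipoprotein list (0.00863) did so with depth as a covariate. In estimated reads the brush border list did (0.0239).

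Of 36 mitotic genes, 23 rose by small amounts and 0 fell (26 and 1 adjusted over the list alone), with a median log2 fold change of 0.22 in CPM and 0.07 in estimated reads not scaled to library totals, and this was the list with the smallest p (camera adjusted p = 1.46e-07, and adjusted p = 0.732 with an estimated correlation). The checkpoint kinase *BUB1* rose from 125 ± 2.47 to 169 ± 10.3 CPM, a log2 fold change of 0.43 ± 0.05 (limma adjusted p = 0.00308). The spindle protein *DLGAP5* rose from 87.2 ± 4.77 to 130 ± 11.7 CPM and the centromeric histone *CENPA* from 36.5 ± 2.51 to 53.7 ± 3.89 CPM. Of 37 genes of S phase and DNA replication, 7 rose and 0 fell (7 and 0 adjusted over the list alone), with a camera adjusted p of 0.0123, and adjusted p = 0.732 with an estimated correlation. Cyclin E gene *CCNE1* rose from 46.6 ± 3.22 to 82.3 ± 7.54 CPM, a log2 fold change of 0.81 ± 0.08 (limma adjusted p = 0.00224). The S phase median was 0.09 in CPM and -0.05 in estimated reads not scaled to library totals. The mitosis and S phase lists both had a median of 0.55 reads per base of transcript. All 2355 genes at 0.4 to 0.6 reads per base had the same medians as S phase, 0.09 and -0.05, with 388 higher and 190 lower. The S phase shift cannot be told apart from this trend with reads per base. The camera adjusted p of the S phase list was 0.0588 without uninfected library 3 and 0.114 with uninfected libraries 3 and 4 left out. It was 0.063 after cyclic loess, 0.42 in estimated reads and 0.916 among genes under 0.2 reads per base. Of 17 histone genes, 1 rose and 1 fell (0 and 1 adjusted over the list alone), with a median of 0.06, a mean of -0.03 and a test direction of higher (camera adjusted p = 0.711), which turned to lower with depth as a covariate (0.00863).

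Inflammatory genes changed in part. Of 27 NF-kB targets and cytokines, 10 rose and 2 fell (10 and 2 adjusted over the list alone), with a camera adjusted p of 0.0274, and adjusted p = 0.732 with an estimated correlation. *BIRC3*, an inhibitor of apoptosis (chromosome 11, 102317450 to 102339403), rose from 46.0 ± 4.02 to 144 ± 22.9 CPM, a log2 fold change of 1.62 ± 0.11 (limma adjusted p = 0.00129). *TNFAIP3*, which restrains NF-kB signalling, rose from 86.9 ± 5.94 to 131 ± 9.0 CPM and the NF-kB subunit *RELB* from 44.1 ± 3.16 to 62.9 ± 2.6 CPM. The list's camera adjusted p was 0.0632 without infected library 1, 0.0588 on ranks, 0.0616 with uninfected libraries 3 and 4 left out and 0.152 among genes under 0.2 reads per base. Of 28 genes of the type I and III interferon response, 6 fell and 0 rose (5 and 0 adjusted over the list alone, camera adjusted p = 0.136), and the viral RNA sensor *DDX58* fell from 37.9 ± 0.698 to 27.7 ± 1.83 CPM. That list passed as lower with uninfected libraries 1 and 2 left out (camera adjusted p = 0.0182) and with depth as a covariate (0.0285). Of 21 genes of the interferon gamma response and antigen presentation, 2 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.497), and the peptide transporter *TAP1* rose from 31.2 ± 3.06 to 53.7 ± 4.07 CPM. Of 17 antimicrobial and mucosal defence genes, 4 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 0.467), with *S100A9*, a calprotectin subunit, rising from 16.8 ± 1.85 to 25.9 ± 1.1 CPM. Of 26 immediate early genes, 3 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.0566). The immediate early list passed as higher without uninfected library 3 (camera adjusted p = 0.00228) or 4 (0.00497) and with both left out (1.02e-08). It did so with no filter (0.00769), with the replicate number as a block (0.00161), after upper-quartile rescaling (0.0496) and in estimated reads (0.0236). It passed as lower with depth as a covariate (0.0322).

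In the list of extracellular matrix and TGF-beta targets 9 of 26 genes rose and 2 fell (15 and 4 adjusted over the list alone), with a camera adjusted p of 0.0187, and adjusted p = 0.732 with an estimated correlation. The urokinase gene *PLAU* rose from 9.22 ± 2.28 to 25.6 ± 1.6 CPM, a log2 fold change of 1.41 ± 0.18 (limma adjusted p = 0.00342). The hemidesmosomal collagen *COL17A1* (chromosome 10, 104031286 to 104086002) fell from 72.0 ± 11.3 to 20.3 ± 0.329 CPM, a log2 fold change of -1.76 ± 0.12 (limma adjusted p = 0.00115), and the basement membrane collagen *COL4A2* from 12.2 ± 1.34 to 5.38 ± 0.334 CPM. Without uninfected library 2 the list's camera adjusted p was 0.0611, with uninfected libraries 1 and 2 left out it was 0.21, and among genes under 0.2 reads per base it was 0.223. Its direction turned to lower with depth as a covariate (camera adjusted p = 0.587). Of 25 Wnt targets and intestinal stem cell genes, 4 rose and 5 fell (5 and 5 adjusted over the list alone), with a median of 0.01, a mean of 0.03 and a test direction of lower (camera adjusted p = 0.917). Within it the hyaluronan receptor *CD44* (chromosome 11, 35138870 to 35232402) rose from 33.6 ± 1.63 to 78.7 ± 3.75 CPM, a log2 fold change of 1.20 ± 0.07 (limma adjusted p = 0.000875), and the ephrin receptor *EPHB3* from 4.37 ± 1.31 to 14.3 ± 4.15 CPM.

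Genes of xenobiotic metabolism moved in both directions, with 12 of 26 lower and 4 higher (the same adjusted over the list alone), and the list lay lower (camera adjusted p = 0.0259, and adjusted p = 0.732 with an estimated correlation). The glucuronosyltransferase *UGT2A3* fell from 103 ± 2.16 to 65.8 ± 7.87 CPM. *UGT2B17*, whose reads are hard to separate from those of its paralogs, fell from 3.1 ± 0.825 to 0.156 ± 0.152 CPM (limma adjusted p = 0.00217), the latter under the floor of 3 reads, so no fold is given. *CYP1B1*, a target of the aryl hydrocarbon receptor, rose from 3.02 ± 0.32 to 10.5 ± 3.12 CPM, a log2 fold change of 1.49 ± 0.19 (limma adjusted p = 0.00336). The list's camera adjusted p was 0.0517 without infected library 3, 0.102 at a minimum mean of 5, and 0.0607 and 0.065 with uninfected libraries 1 and 2 or 3 and 4 left out. It was 0.186 in estimated reads, 0.0783 among genes under 0.2 reads per base and 0.259 with depth as a covariate. Of 26 liver-type secreted proteins, 6 fell and 0 rose (the same adjusted over the list alone, camera adjusted p = 0.303), and the antithrombin gene *SERPINC1* fell from 28.6 ± 1.13 to 19.2 ± 0.0684 CPM.

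Stress and metal genes gave mixed counts. Of 19 tested metallothioneins and metal handling genes, 6 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 0.0912). The metallothionein *MT1G* rose from 0.925 ± 0.447 to 5.7 ± 0.718 CPM, a log2 fold change of 1.82 ± 0.20 (limma adjusted p = 0.0023), and *MT1X* from 7.83 ± 1.4 to 15.2 ± 1.41 CPM, values that are uncertain where reads fall in near-identical family members. The list passed with no filter (0.0092) and with uninfected libraries 3 and 4 left out (0.0246). Of 24 NRF2 targets, 6 rose and 5 fell (10 and 5 adjusted over the list alone, camera adjusted p = 0.155). The thioredoxin reductase *TXNRD1* rose from 164 ± 4.45 to 217 ± 7.46 CPM, and the aldo-keto reductase *AKR1C2*, uncertain among its paralogs, fell from 63.7 ± 1.31 to 34.7 ± 3.45 CPM. Of 28 ATF4 and amino acid response genes, 7 fell and 1 rose (the same adjusted over the list alone, camera adjusted p = 0.223), with *STC2* falling from 206 ± 12.1 to 147 ± 5.35 CPM and the leucine sensor *SESN2* from 67.5 ± 4.44 to 43.4 ± 3.27 CPM. That list passed in estimated reads (0.0281), after the correction for 1 read per position (0.0264) and with depth as a covariate (0.0396). Of 22 unfolded protein response genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.0828), and this list passed without uninfected library 3 (camera adjusted p = 0.0168), uninfected library 4 (0.0111) or infected library 1 (0.037). It also passed with uninfected libraries 3 and 4 left out (6.88e-05), with no filter (0.0142) and with the replicate number as a block (0.00773). It passed as lower with depth as a covariate (0.00693). Of 29 p53 targets and apoptosis genes, 6 rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 0.266), with the death ligand *TNFSF10* falling from 9.78 ± 1.73 to 4.53 ± 0.642 CPM. Of 30 calcium genes, 1 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.688), the latter being the vitamin D-responsive calbindin *S100G*, which fell from 1.96 ± 0.887 to 0.244 ± 0.093 CPM. The calcium list passed as lower with depth as a covariate (0.0471).

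Of 36 endosomal genes, 4 rose and 5 fell (6 and 5 adjusted over the list alone, camera adjusted p = 0.155), and the sorting nexin *SNX1* fell from 115 ± 7.52 to 89.3 ± 3.77 CPM. In the lysosome list 2 of 28 rose and 3 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.266), and the chloride transporter *CLCN7* fell from 150 ± 12.8 to 80.7 ± 23.9 CPM. In the autophagy list 4 of 26 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.303), and *ATG13* fell from 147 ± 2.69 to 123 ± 0.227 CPM. For fatty acid synthesis and storage 1 of 20 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 0.303), and for fatty acid oxidation and ketogenesis 1 of 25 rose and 3 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.312). Of 33 genes of ribosome biogenesis and nucleotide synthesis, 3 rose and 0 fell (2 and 0 adjusted over the list alone), with a median of -0.02, a mean of -0.04 and a test direction of higher (camera adjusted p = 0.504). *IMPDH1*, of guanine nucleotide synthesis, rose from 74.5 ± 5.67 to 97.0 ± 1.97 CPM. The list passed with depth as a covariate (1.75e-06). With uninfected libraries 3 and 4 left out the lysosome (0.0475), fatty acid synthesis (0.023) and fatty acid oxidation (0.0392) lists passed as higher. With no filter the endosomal list did (0.0462), and with depth as a covariate fatty acid oxidation passed as lower (0.0396).

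A further 7 lists of mostly abundant genes lay higher in infected cells by small amounts. Of 40 cytosolic ribosomal protein genes, 6 rose and 0 fell (3 and 0 adjusted over the list alone, median 0.15, camera adjusted p = 1.9e-05). For nuclear oxidative phosphorylation 3 of 44 rose and 1 fell (0 and 0 adjusted over the list alone, median 0.15, camera adjusted p = 0.000221). For glycolysis and hypoxia targets 5 of 33 rose and 0 fell (0 and 0 adjusted over the list alone, median 0.18, camera adjusted p = 0.000271), *HK1* among them. For housekeeping genes 1 of 24 rose and 0 fell (0 and 0 adjusted over the list alone, median 0.14, camera adjusted p = 0.00158). For heat shock and chaperones 5 of 20 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.16, camera adjusted p = 0.00392). For cholesterol synthesis 1 of 24 rose and 0 fell (0 and 0 adjusted over the list alone, median 0.27, camera adjusted p = 0.00658), and for the 13 mitochondrially encoded genes 0 rose and 0 fell (0 and 0 adjusted over the list alone, median 0.13, camera adjusted p = 0.0247). All 7 had adjusted p = 0.732 with an estimated correlation. The mitochondrially encoded list did not pass without uninfected library 1 (camera adjusted p = 0.0694), uninfected library 2 (0.0611), infected library 2 (0.0509) or infected library 3 (0.0517). Nor did it after cyclic loess (0.0674) or after the correction for 1 read per position (0.115). In estimated reads camera adjusted p was 0.121 for oxidative phosphorylation, 0.356 for housekeeping genes, 0.084 for heat shock and 0.479 for the mitochondrially encoded genes. Among genes under 0.2 reads per base it was 0.0673 for glycolysis. With uninfected libraries 1 and 2 both left out, camera adjusted p was 0.21 for glycolysis, 0.434 for cholesterol synthesis, 0.142 for heat shock and 0.26 for the mitochondrially encoded genes. With depth as a covariate the direction turned to lower for cholesterol synthesis (camera adjusted p = 0.0207), glycolysis (0.0163) and the mitochondrially encoded genes (0.767). The ribosomal (0.154), oxidative phosphorylation (0.45), housekeeping (0.767) and heat shock (0.915) lists did not pass with it. These lists had median depths of 0.49 to 0.89 reads per base of transcript, and in estimated reads not scaled to library totals their medians were 0.01, 0, 0.03, -0.01, 0.01, 0.12 and -0.02 in the same order.

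Across genes, the median fold change went up with the reads per base of transcript. The median log2 fold change was -0.18 over 2594 genes under 0.02 reads per base and 0.13 over 1426 genes at 0.6 or more, and in estimated reads the medians were -0.43 and -0.01, while the median of all tested genes went from 0.01 to -0.12. Of 18132 genes with a transcript length, 13 (0.0717%) exceeded 1 read per base. The mitochondrially encoded transcripts took 0.0679 ± 0.00245% of the values in uninfected and 0.0745 ± 0.00357% in infected libraries, a difference of 0.00659 percentage points (exact two-sided permutation p = 0.114, n = 4 and 3, smallest possible p 0.0571). The estimated reads in these 13 genes were 10243 ± 31.2 in uninfected and 10165 ± 36.4 in infected libraries, a difference of -78.1 (exact two-sided permutation p = 0.0571, the smallest possible). The higher share thus went with fewer reads in total and not with more estimated reads in these genes. However, these genes lay at 0.68 to 0.97 reads per base in every library. Under a limit near 1 read per base their reads could hardly rise, so the values cannot show whether these transcripts changed.

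**Figure D3:**
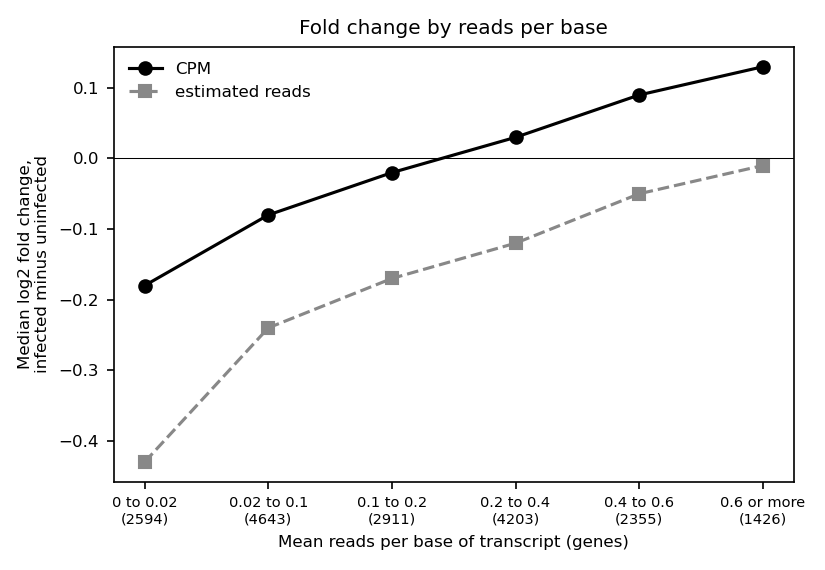
Median log2 fold change of genes grouped by estimated reads per base of transcript, in CPM and in estimated reads not scaled to library totals. In CPM the medians run from -0.18 to 0.13, and in estimated reads from -0.43 to -0.01.

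Lists of markers of other cell types held few tested genes. Of 14 goblet cell genes, 1 fell and 0 rose (the same adjusted over the list alone, camera adjusted p = 0.504). Of 10 enteroendocrine and tuft cell genes, 2 rose and 2 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.566). Of 6 fibroblast and stroma genes, 2 fell and 0 rose (the same adjusted over the list alone, camera adjusted p = 0.406). Of 5 blood cell genes, 2 rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 0.118). The latter were *LYZ*, also in the antimicrobial list, and the alpha-globin gene *HBA1*, which rose from 7.81 ± 0.758 to 15.3 ± 0.516 CPM and is uncertain beside its near-identical copy *HBA2*. *LYZ* rose from 66.7 ± 2.85 to 81.4 ± 4.77 CPM, and its limma adjusted p was 0.0691 without infected library 2 and 0.0647 without infected library 3.

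Over the alternatives other than the estimated correlation, the call of the mitosis list held in 24 of 24 (highest camera adjusted p 0.000143). It held in 23 of 24 for ribosomal proteins (highest 0.154), 23 of 25 for digestive enzymes (0.2), 22 of 24 for oxidative phosphorylation (0.45), cholesterol synthesis (0.434) and housekeeping genes (0.767). It held in 22 of 25 for transcription factors (0.295) and glycolysis (0.21). It held in 21 of 24 for heat shock (0.915), 21 of 25 for NF-kB targets (0.152) and extracellular matrix (0.587), 20 of 25 for S phase (0.916), 18 of 25 for xenobiotic metabolism (0.259) and 15 of 24 for the mitochondrially encoded genes (0.767). With an estimated correlation, none of these 14 lists passed (camera adjusted p = 0.732 for each). The estimates ran from -0.01 for NF-kB targets to 0.98 for the mitochondrially encoded genes, against the preset 0.01. The alternatives reuse the same libraries, so these counts are no separate support.

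**Figure D4:**
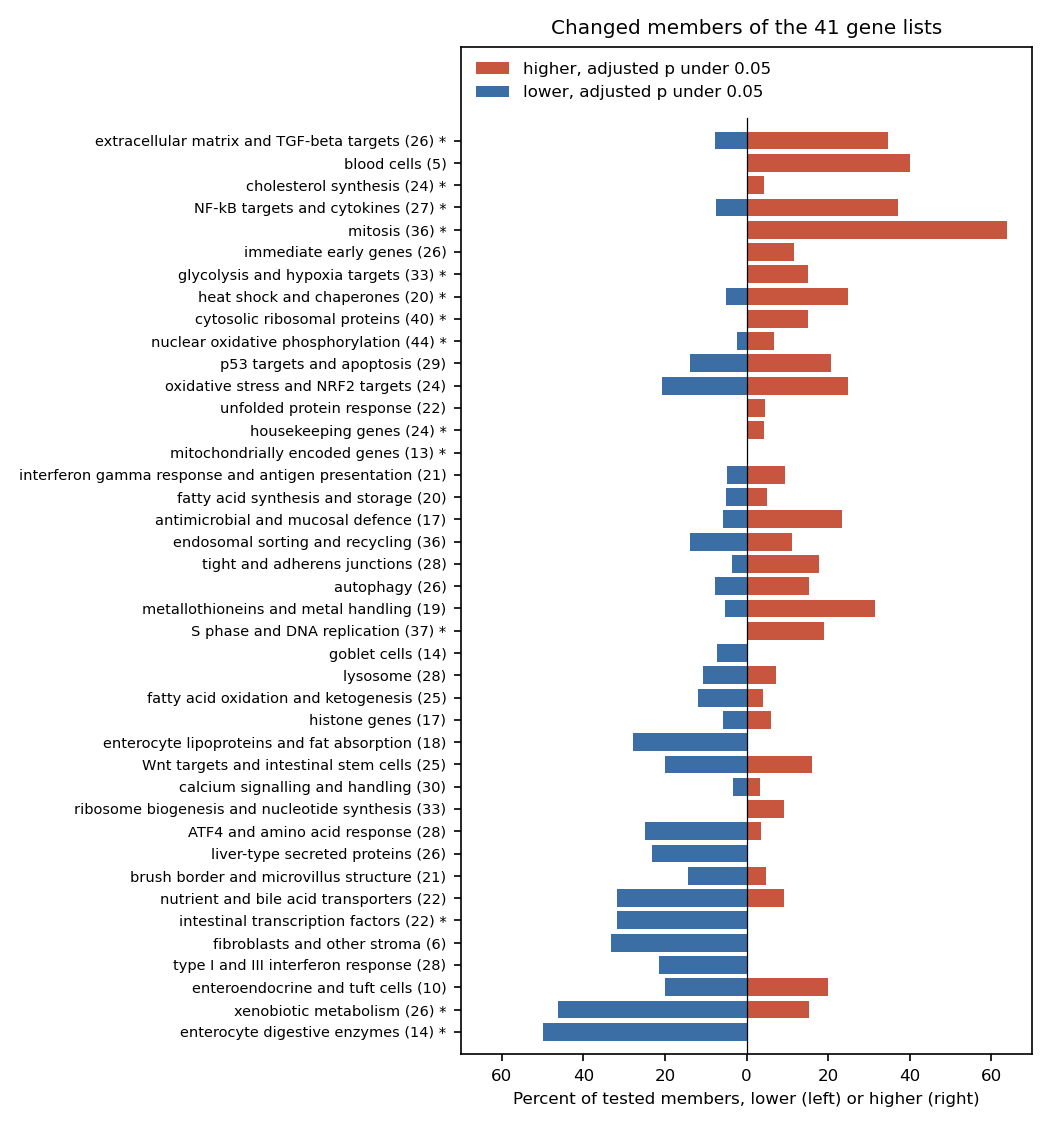
Percent of the tested members of each of the 41 gene lists that were higher (bars to the right) or lower (bars to the left) in infected cells at a limma adjusted p under 0.05, with the number tested in parentheses and lists ordered by median log2 fold change. An asterisk stands for a camera adjusted p under 0.05, reached by 11 lists as higher and 3 as lower. The mitosis list has the longest bar, 23 of 36 genes higher.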

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

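The test of spread within the uninfected libraries was planned, and no explanation was tested for these values. In 5 of the 148 results checked, a single uninfected library lay far from the other 3, with a gap to its nearest neighbour, divided by the whole range, above Dixon's 95% critical value. Chance gives about 1 in 20, a larger share than 5 of 148, so these values need not be more than chance. *NPTX1* was 2.32 CPM in uninfected library 1 and 1.53 to 1.66 CPM in the others (gap 0.836 of the range). *BDH1* was 61.3 CPM in uninfected library 1 against 65.8 to 66.5 CPM (0.867), and *S100A4* 19.6 CPM in the same library against 22.4 to 22.8 CPM (0.885). *CENPA* was 32.7 CPM in uninfected library 4 against 37.3 to 38.1 CPM (0.86). *FOXA3* was 51 CPM in uninfected library 3 against 44.3 to 45.2 CPM (0.859).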

How the results depend on the processing

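Of the alternatives, those that left out pairs of uninfected libraries, cyclic loess, unscaled estimated reads, the restriction to genes under 0.2 reads per base, the correction for 1 read per position and the depth covariate were chosen after the data were seen. In none of the alternatives fitted gene by gene was a gene called in the opposite direction to its call among the 4472, and the cause of each change below was not tested except where the alternative's construction shows it. The number of genes changed at least 2-fold went from 638 to 1059 with a pseudocount of 0.1 and 181 with 5, since the pseudocount shrinks folds of low values, and to 417 at a minimum mean of 5, which tests fewer genes. A test against a 1.5-fold change, which counts genes by a test and not by an estimated fold, gave 26. With the replicate number as a block (uninfected library 4 left out) 2878 genes were called, 1212 of them higher. Whether the numbers pair the samples is unknown, since the labels do not say. The deviations of same-numbered libraries correlated at 0.33, -0.25 and 0.24, and not every sample correlated best with its own number. With so few libraries, these correlations cannot show whether samples were handled in pairs. Leaving out each library in turn gave 1405 to 5160 genes (566 to 2417 higher, 839 to 2743 lower, 332 to 876 at least 2-fold), 12 to 17 gene lists, 57.7 to 70% of variance on the leading component and a mitochondrial share difference of 0.00497 to 0.0085. Without uninfected libraries 3 and 4 there were 6866 genes (3840 lower, 1260 at least 2-fold), and without 1 and 2 there were 3382, of which 2527 were among the 4472. Estimated reads gave 823 higher genes, so 20.8% of calls were higher against 47%, with the median of all genes at -0.12, and *NCL* at -0.01. The 10148 genes under 0.2 reads per base gave 2410 calls (856 higher, 1554 lower) and 0 lists, with fewer genes tested. With depth as a covariate there were 555 calls (275 higher, 280 lower, 185 at least 2-fold), and camera directions turned for immediate early genes (adjusted p = 0.0322), cholesterol synthesis (0.0207), fatty acid oxidation (0.0396), glycolysis (0.0163), mitochondrially encoded genes (0.767), the unfolded protein response (0.00693), calcium (0.0471), histones (0.00863) and extracellular matrix (0.587). An estimated correlation gave 0 lists and ranks 13, and the 500 most variable genes gave 77.1% on the leading component. The mitosis list passed in every alternative in which it was tested except the estimated correlation. Of 129 named genes with a call, 70 kept it whichever library was left out and 39 kept it with the depth covariate. The planned tests on counts were not run because the values are fractional. Few reads limit genes near the floor of 3 reads, and a limit near 1 read per base would compress folds of abundant genes. The steadiness of reads under such a limit was tested on the mitochondrially encoded genes alone (10128 to 10275 reads in every library). Over all tested genes with a length, 13 of 18132 exceeded 1 read per base.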

Other observations

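The gene families below were found by looking through all families after the result was seen. The tests of them, of the pairs of uninfected libraries, of libraries at equal depth, of the abundant genes and of the counts over splits of the libraries were chosen then. For the depth covariate, the count of 555 had been seen and the counts of the other splits had not. Solute carriers fell more often than other protein-coding genes, 61 of 279 (21.9%) against 12.8% (Fisher's exact test, 134 tests, adjusted p = 0.00148), while 31 rose. They included the phosphate transporter *SLC17A4*, from 32.5 ± 6.76 to 8.05 ± 0.629 CPM, the sulfate transporter *SLC26A1*, from 26.2 ± 5.63 to 6.44 ± 2.56 CPM, the glycine transporter *SLC6A9*, from 87.7 ± 21 to 26.0 ± 10.5 CPM, and the sodium-coupled sugar transporters *SLC5A2*, from 18.9 ± 1.8 to 7.58 ± 1.16 CPM, and *SLC5A9*, from 65.3 ± 13.2 to 30.4 ± 2.77 CPM. Within strata of reads per base the exact p for the family was 2.02e-05, and leaving out each library in turn gave 6.25e-07 to 0.00169. The count was 26 of 279 (9.32% against 4.8% of the others) without infected library 2 and 25 of 279 (8.96% against 4.65%) without infected library 3. With depth as a covariate, when fewer genes were called in all, it was 9 of 279 (3.23% against 1.78%, Fisher's exact test p = 0.0679). The tests of this family and of those below count genes as independent, although all calls come from the same 7 libraries. The stratified and leave-one-out p are not adjusted for the 134 tests. They reuse the data in which the families were found, so they are no separate support.

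Cytochrome P450 genes fell in 11 of 28 cases (39.3% against 12.9%, Fisher's exact test adjusted p = 0.0145, stratified exact p = 0.00122), while 4 rose. *CYP4F3*, of leukotriene and fatty acid hydroxylation, fell from 38.8 ± 13.8 to 10.9 ± 2.29 CPM, *CYP17A1*, of steroid synthesis, from 5.13 ± 1.35 to 1.02 ± 0.299 CPM, and *CYP2C19* from 7.65 ± 2.02 to 0.534 ± 0.494 CPM, with paralogs of these subfamilies open to shared reads. Leaving out each library in turn gave stratified exact p from 5.88e-05 to 0.00291, and with depth as a covariate 2 of 28 fell (7.14% against 1.8%, Fisher's exact test p = 0.0909). Zinc finger genes named ZNF fell in 93 of 445 cases (20.9% against 12.7%, Fisher's exact test adjusted p = 0.000189, stratified exact p = 0.00518). They fell in 193 of 445 (43.4%) with uninfected libraries 3 and 4 left out (Fisher's exact test p = 2.28e-30), but in 44 of 445 with uninfected libraries 1 and 2 left out (p = 0.587), 24 without infected library 2 (p = 0.341), 22 without infected library 3 (p = 0.448), 45 of 440 without uninfected library 1 (p = 0.0287) and 49 of 443 without uninfected library 2 (p = 0.053), and in 4 of 445 with depth as a covariate (p = 0.963). ZBTB genes fell in 15 of 40 cases (Fisher's exact test adjusted p = 0.00342, stratified exact p = 0.000531) and in 17 with uninfected libraries 3 and 4 left out (Fisher's exact test p = 0.000931), but in 8 with uninfected libraries 1 and 2 left out (p = 0.044), 3 without infected library 2 (p = 0.312), 4 without infected library 3 (p = 0.119), 6 without uninfected library 1 (p = 0.0824), 9 without uninfected library 4 (p = 0.00792), 10 without uninfected library 2 (p = 0.00191) and 0 of 40 with depth as a covariate (p = 1).

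The group split was set against the other splits of the 7 libraries into 4 and 3. With limma, of the 35 splits 1, the real one, gave as many called genes (4472, highest other 0), higher genes (2103, highest other 0), lower genes (2369, highest other 0) or genes changed at least 2-fold (638, highest other 0). That is the smallest share the splits allow. A split that mixes the groups also puts their difference into its error, which lowers its count. The share speaks against chance only if the libraries are exchangeable. Near-duplicate pairs put that in doubt, since the chi-square per degree of freedom was 2.82 for uninfected libraries 1 and 2, 2.88 for 3 and 4 and 3.19 for infected libraries 2 and 3, against 7.85 to 19.04 for the other pairs within a group. At an unadjusted p under 0.05 the real split had 7628 genes and the highest other, uninfected libraries 1, 2 and 4 against the rest, 5976. For the gene lists, 14 of 35 splits gave as many calls as the 14 of the real split, the highest other being 28, so chance is not excluded for the number of lists.

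The 4472 genes were called while the infected libraries were also shallower, apart from infected library 1, which was about as deep as uninfected library 3. With depth as a covariate, 555 genes were called in the real split, and the split of uninfected libraries 1 and 2 and infected library 1 against the rest gave 1876, so depth as the whole cause is not excluded, and that other split points to a structure of the samples. At about equal depth, infected library 1 against uninfected library 3, 73.7% of the 6144 genes called in the other 5 libraries went the same way (78.7% of the 1195 at least 2-fold, 61.4% of all tested). With 1 library on each side, and with these 2 far apart on the component that separates the uninfected pairs (15.6 and -27.8), this decides nothing about depth. The median absolute log2 fold change of the 4472 genes went from 0.54 (SE 0.12) to 0.32 (SE 0.15), with 98.8% keeping their sign and 399 their call, so the calls ended because the estimate shrank and its error grew. Within the uninfected libraries 67.5% of the called genes moved with depth in the direction of the infection difference. Within the infected libraries 78.6% did so. However, depth also sets the uninfected pairs apart, and it sets infected library 1 apart from the other infected libraries. These shares therefore cannot tell depth from those differences between libraries. No share over all tested genes is given for comparison. Depth also goes largely with group, so depth as part of the cause cannot be told apart from infection. The depth used here counts reads assigned to human genes, and whether infection itself lowered it was not tested. If it did, the covariate would also remove part of an infection difference. Infection itself stays open as an untested explanation.

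The uninfected libraries fell into pairs, 1 with 2 and 3 with 4. The chi-square per degree of freedom was 2.82 and 2.88 within the pairs and at least 14.82 across them. After cyclic loess 5215 genes were called between the pairs, against 5797 before, which argues against a trend with abundance as the whole cause. A label swapped between the groups needs a library out of place in each. Uninfected library 3 correlated more with infected library 1 (0.983) than with uninfected library 2 (0.98), but 0 infected libraries correlated less with an infected library (lowest 0.987) than with an uninfected one (highest 0.983), which argues against such a swap and not against a single wrong label. A batch or culture difference that the labels do not name may underlie the pairs, and the value of 14.82 cannot tell these apart because no label gives a batch or date. No biological explanation was tested.

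Abundant genes lay slightly higher in infected cells. Over 1426 genes at 0.6 reads per base or more the median log2 fold change was 0.13 in CPM and -0.01 in estimated reads. Leaving out the scaling moves all genes (their median from 0.01 to -0.12), so the value in estimated reads does not test a limit near 1 read per base together with fewer reads in the infected libraries. In the 13 mitochondrially encoded genes, which lie near that limit, the estimated reads ran from 10128 to 10275, a range of 1.44% of their mean, while the depth of the libraries ranged over 18.7% of its mean. Such steady reads are what a limit in these 13 genes would give, and the steadiness was not tested on the other abundant genes. Over all tested genes with a length, however, only 13 of 18132 exceeded 1 read per base. The highest value in each library, that of *AHNAK*, was 675.3 CPM in infected library 1 to 862.9 CPM in uninfected library 3. A limit over all genes would give such values, so the levels and folds of abundant genes may be compressed. After a correction for 1 read per position the median was 0.14, but at a median of 0.71 reads per base the measure would be close to saturation under such a limit, so more of these transcripts in infected cells cannot be told apart from the read limit. The medians of the ribosomal (0.15), housekeeping (0.14) and mitochondrially encoded (0.13) lists were of this size.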
